A study of Mus musculus with 13 samples.

How the data were processed

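RNA was measured in whole implantation sites, the swellings of the uterus that hold an implanted embryo with the maternal tissue around it, on 13 Affymetrix Mouse430_2 arrays. Per the labels' protocols, embryos were transferred to ICR mice on day 3 of pseudopregnancy. Mouse embryos had been flushed on day 4 of pregnancy and rat embryos, from Wistar rats, on day 5. About 100 mg of tissue was extracted with TRIzol and purified on RNeasy columns, and about 8 µg of total RNA was made into biotin-labelled cRNA. The 6 groups were mouse sites, rat sites, and rat sites from uteri that also received mouse embryos (called rat sites after co-transfer), each collected on day 7 or day 9. The group of rat sites after co-transfer on day 7 had 3 arrays, and each other group had 2. The labels do not say that the arrays of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

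The deposited values are MAS5 intensity values on a linear scale, per the submitters' processing notes, with 1 signal for each of 45101 probe sets. The version of MAS5 is not given in the sources used here, and detection calls were not used here. On every array, the mean of the deposited values after leaving out the lowest and highest 2 percent was 500, so each array had been scaled to the same target before deposit. The small experiment files deposited with the arrays hold settings of the instruments and no expression values. They showed 1 fluidics protocol, 2 hybridisation dates and 2 scanners. The wash runs were inferred from the recorded hybridisation times, where a longer gap between arrays was taken to start a new run. This gave 4 runs. Run 1 held the mouse and the rat sites of day 7. Run 2 held replicates 1 and 2 of the rat sites after co-transfer on day 7 with the mouse sites of day 9. Run 3 held the rat sites and the rat sites after co-transfer of day 9, and replicate 3 of the rat sites after co-transfer on day 7 was processed alone in run 4, on the other date and scanner. Rat and mouse sites of day 7, and the 2 groups of rat sites on day 9, were therefore each compared within 1 run. In every other comparison wash run and group cannot be told apart.

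The array's probes match mouse transcripts, and no sequences of the probes or of rat transcripts were used here. A low signal in a rat site can therefore reflect a rat transcript that binds mouse probes poorly, and signals of maternal genes come from mouse tissue in all groups. Gene symbols were taken from the platform annotation. It gave 1 symbol for 34958 probe sets, several for 932 and none for 9211, and 0 symbols changed when looked up through their Entrez numbers. No gene was named from a probe set with several symbols. No genome build is named in the files, so no coordinates are given.

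Signals were transformed to log2(signal + 57.1), the pseudocount being the 25th percentile of all values. Fold changes are on this scale, which understates the change of dim probe sets. The 64 AFFX control probe sets were left out of the tests, and a probe set was tested if it lay above the 60th percentile of its array on at least 2 arrays. This left 22155 probe sets, of which 19220 had 1 symbol, for 12010 genes. Genes high in only 1 group could pass this filter through its arrays alone, so list changes against that group are partly built in. Group means were fitted to all 13 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), since groups of 2 need a shared estimate of the spread. The fit had 7 residual and 2.71 prior degrees of freedom, and the number of arrays limits its precision. The 9 comparisons were the 3 contrasts between groups on each day and the change from day 7 to day 9 in each group. In addition, 3 interactions tested whether a difference between groups changed between the days. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a probe set was called at an adjusted p under 0.05.

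Before the data were examined, the groups, the design, the alternatives, 23 gene lists and the rule for naming genes were fixed. Each gene entered a list once, through its tested probe set with the highest mean log2 signal. The lists were tested with limma's camera at a preset correlation between genes of 0.01, with the adjustment over the lists within a comparison, and again with an estimated correlation. A list needed 5 measured genes, which 1 list (T and B cells, with 4) did not reach. Of the 109 calls among 198 list tests, 90 held with the estimated correlation. List p-values are those of camera with the preset correlation unless stated otherwise, and the estimated correlation can give far larger ones. Named genes are the 6 largest rises and 6 largest falls in each comparison within a day, and, in the same comparisons, up to 2 called members of each list with the largest change. For the change between days the 4 largest in each direction were taken, and for the interactions the 3 largest. The largest rises and falls, outside the interactions, had to come from groups whose arrays did not overlap, and provisional gene names were skipped. Overlaps between comparisons that share arrays were set beside 100 simulations of unchanged groups (correlation and covariance only, since unchanged groups give almost no calls) and beside the product of the numbers of calls divided by the number tested.

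The limma step was tested on simulated data for the comparison of rat with mouse sites on day 7. Among 22155 probe sets it recovered 9 of 67 changes of 0.5 on the log2 scale (13.4%), 49 of 67 changes of 1 (73.1%) and 65 of 66 changes of 2 (98.5%), and it called 9 probe sets with no change. Few probe sets carried a planted change, while 24.3% were called in the data, so the adjusted threshold was stricter in the simulation. These shares are therefore not the sensitivity of the real comparison. Alternatives were quantile normalization, a pseudocount 4 times larger, a floor, no filter on dim probe sets, only the arrays compared, leaving out probe sets shared by transcripts, the replicate number as a block, the hybridisation date as a block, array weights, and leaving out each array in turn. Only replicate 3 of the rat sites after co-transfer on day 7 lay on the other date. The date as a block therefore only sets that array aside and makes no adjustment among the other arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.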

Results

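Gene expression in whole implantation sites was compared between mouse embryos, rat embryos, and rat embryos carried beside mouse embryos, all in mouse uteri, on day 7 and day 9. The comparisons ask how the implantation site of a foreign embryo differs from that of a mouse embryo, and whether mouse embryos in the same uterus change the site of the rat embryo. Each array held 45101 signals with a trimmed mean of 500, and medians ran from 141.2 to 204.5. Arrays of a group correlated with r between 0.968 and 0.982 across the tested probe sets, which are not independent replicates.

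On day 7 the arrays of both groups of rat sites correlated with a mean r of 0.970, and with mouse sites at 0.932 for rat sites and 0.925 after co-transfer. On day 9 the mean r was 0.935 between rat sites after co-transfer and mouse sites, 0.857 between rat and mouse sites, and 0.868 between both groups of rat sites.

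**Figure D1:**
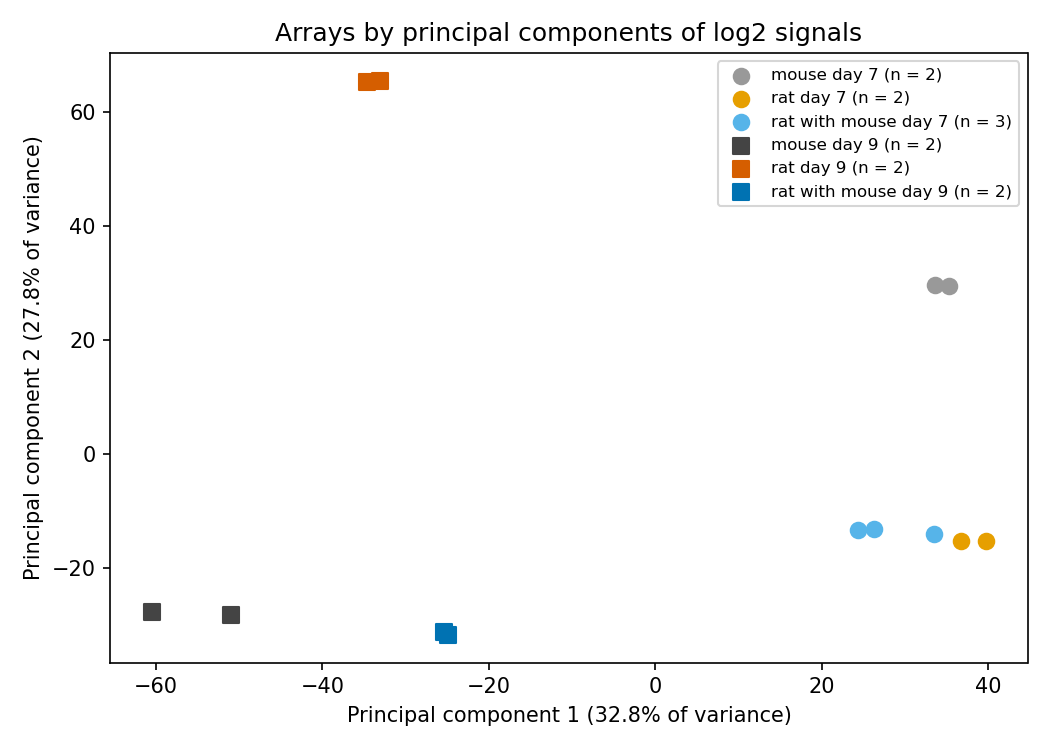
Each point is 1 array, placed by principal component 1 (32.8% of the variance) and component 2 (27.8%) of the log2 signals of the tested probe sets; circles are day 7, squares day 9, and colours the 6 groups. Day 7 arrays lie on the right, and the rat sites of day 9 lie alone at the top left.

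The control probe sets of the mouse sites of day 7 differed from those of the other arrays. Their Gapdh 3' to 5' ratios were 1.54 and 1.44, against 2.56 to 4.07 elsewhere, while their Actb ratios were 3.47 and 3.71, against 2.36 to 3.34. Their 18S rRNA 3' signals were 2461.6 and 1072.8, against 3684.4 to 5756.1. The rat sites of day 9 had 18S rRNA middle signals of 6737.2 and 6209.4, against 522.4 to 1933.1 on the other arrays.

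**Figure D2:**
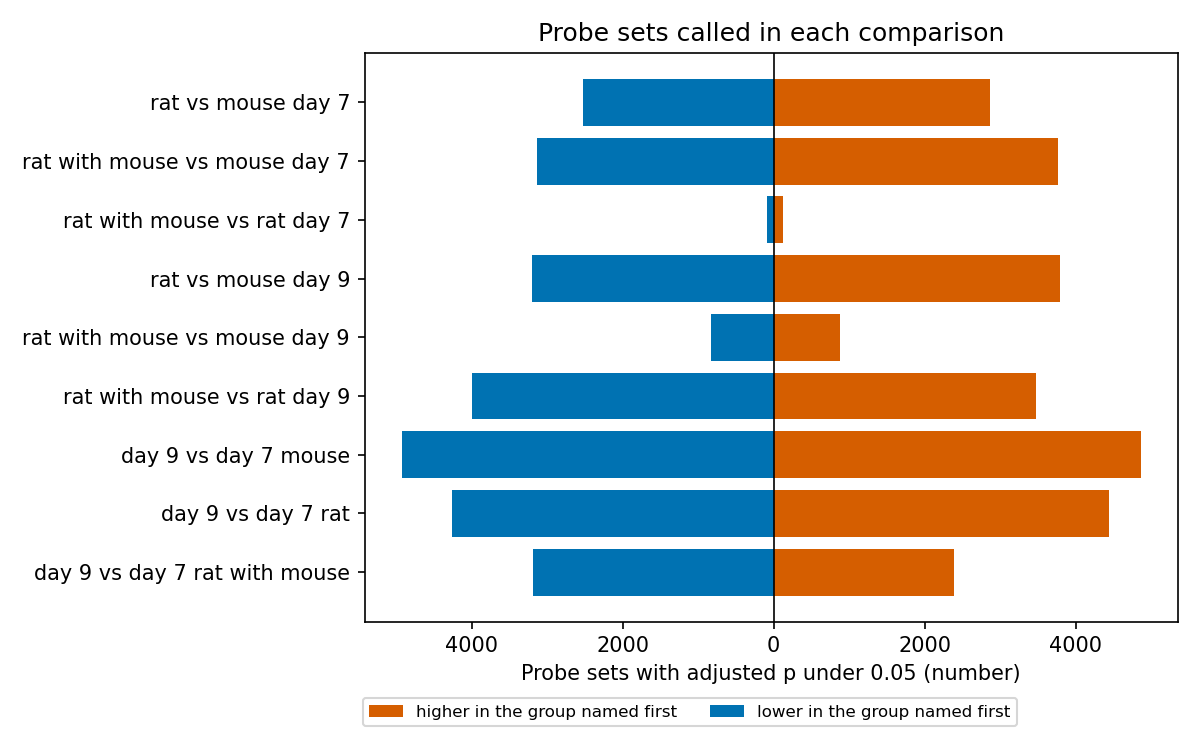
Bars give the number of probe sets with a limma adjusted p under 0.05 in each comparison, to the right for those higher in the group named first and to the left for those lower. The comparison of both groups of rat sites on day 7 has 214 calls, and the change from day 7 to day 9 in mouse sites has 9789.

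The first comparison asked how rat sites differed from mouse sites on day 7. Rat sites had lower signals of gene lists for acute inflammation, epithelium, hypoxia and the immediate early response. Lcn2 (lipocalin 2, an antimicrobial protein of epithelium and neutrophils) was at 218 ± 33.2 in rat sites (SD, n = 2) and at 7520 ± 15.5 in mouse sites (n = 2), a log2 change of -4.79 (SE 0.23, adjusted p = 2.08e-06). Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, fell from 5252 ± 313 to 275 ± 71.8, and the collagenase gene Mmp13 fell from 891 ± 27.8 to 8.85 ± 3.04, below the pseudocount. In the opposite direction, Prl3c1, a prolactin family hormone of the decidua, was at 9761 ± 143 against 1800 ± 172 (log2 change 2.41, SE 0.29, adjusted p = 0.000344), and the metallothionein gene Mt4 at 6371 ± 39.6 against 977 ± 166.

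By list, 26 of 37 hypoxia and glycolysis genes fell and 2 rose (27 and 2 adjusted over the list alone), with a median log2 change of -0.72 (camera adjusted p = 8.03e-15, or 0.00314 with the estimated correlation). Among them were Eno2 (-2.35), a glycolytic enzyme, and Egln3 (-2.34), a prolyl hydroxylase of the hypoxia response. Of 33 genes of uterine epithelium and glands 19 fell and 3 rose (20 and 4 adjusted over the list alone; median -0.60, adjusted p = 7.23e-08), led by Lcn2 and the cornified envelope gene Sprr2f (-3.67). Of 26 genes of neutrophils and acute inflammation 14 fell and 1 rose (14 and 2 adjusted over the list alone; median -0.65, adjusted p = 1.14e-06). Of 38 immediate early and heat shock genes 19 fell and 1 rose (21 and 4 adjusted over the list alone; median -0.63, adjusted p = 3.57e-07), among them the heat shock gene Hspa1a (-2.77). The mouse sites that form the reference of these lists are the arrays with the unusual Gapdh ratios of 1.54 and 1.44.

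Immune lists were lower in rat sites as well. Of 30 macrophage and dendritic cell genes 12 fell and 1 rose (16 and 1 adjusted over the list alone; median -0.39, adjusted p = 8.02e-06), with the lipopolysaccharide co-receptor gene Cd14 at -1.96. In the list of uterine natural killer cells 9 of 16 fell and 0 rose, the same numbers as adjusted over the list alone (median -0.41, adjusted p = 9.04e-05), with the granzyme gene Gzmc at -0.83. Interferon response genes fell in 16 cases and rose in 1 of 41 (16 and 1 adjusted over the list alone; median -0.27, adjusted p = 3.81e-05), with the GTPase gene Igtp at -2.17. Of 17 genes of MHC class I presentation 6 fell and 1 rose (6 and 2 adjusted over the list alone; median -0.34, adjusted p = 0.00172). In these rat sites several probe sets of the MHC class I gene H2-D1 were high and Tmem14c was low, unlike in every other group. The labels do not tell whether the recipients of these arrays differed. No difference from mouse sites on day 7 can therefore be assigned to embryo species alone. Of 45 extracellular matrix genes 20 fell and 6 rose (21 and 7 adjusted over the list alone; median -0.21, adjusted p = 6.84e-05), a call lost with the estimated correlation (adjusted p = 0.0713 with an estimated correlation). Cell cycle genes were the list that rose: 16 of 49 rose and 0 fell (18 and 0 adjusted over the list alone; median 0.34, adjusted p = 6.18e-06), with Ccna2, the cyclin of S and G2 phase, at 0.84. The lists of decidual stroma (8 rose and 6 fell of 26; adjusted p = 0.357) and of trophoblast (2 rose and 4 fell of 28; adjusted p = 0.829) did not pass the test.

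In all, limma called 5390 of 22155 probe sets on day 7, 2867 higher and 2523 lower in rat sites, and 1357 of them changed at least 2-fold. All 4 arrays came from 1 wash run. Those arrays alone gave 4069 calls, and 10 of the 11 lists were called again in the same direction. The fold changes are the same in both fits, so this tries only another estimate of the spread. The date as a block, which only sets 1 co-transfer array aside, gave 5309. The number of calls was 3066 without replicate 2 of the mouse sites, 3188 without replicate 1 of the rat sites and 3231 without replicate 2 of the rat sites.

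The second comparison set rat sites after co-transfer against mouse sites on day 7. Prl3c1 was at 10730 ± 742 (n = 3) against 1800 ± 172 (log2 change 2.54, SE 0.26, adjusted p = 0.000105), and Mt4 at 6053 ± 49.9 against 977 ± 166. Sprr2f was lower, at 371 ± 81.0 against 12210 ± 331 (log2 change -4.86, SE 0.14, adjusted p = 1.44e-07). Lcn2 was at 450 ± 145 against 7520 ± 15.5, and Edn1, the vasoconstrictor endothelin 1, at 148 ± 29.6 against 1983 ± 70.1. Of 37 hypoxia and glycolysis genes 29 fell and 2 rose, as also adjusted over the list alone (median -0.87, camera adjusted p = 7.11e-14), among them Egln3 (-2.36) and Ddit4 (-2.33), an inhibitor of mTOR signalling induced by stress. The immediate early and heat shock list fell in 22 of 38 genes and rose in 3 (24 and 3 adjusted over the list alone; median -0.68, adjusted p = 9.8e-08). Extracellular matrix genes fell in 27 and rose in 6 of 45 cases (28 and 7 adjusted over the list alone; median -0.36, adjusted p = 3.31e-07), with Thbs1, the matrix protein thrombospondin 1, at -3.15. The mouse sites with the unusual Gapdh ratios of 1.54 and 1.44 form the reference here too.

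Of 16 natural killer cell genes 9 fell and 0 rose, as also adjusted over the list alone (median -0.60, adjusted p = 1.93e-06), with the granzyme genes Gzmg (-1.44) and Gzmc (-1.15). Of 33 epithelium and gland genes 18 fell and 6 rose (19 and 6 adjusted over the list alone; median -0.49, adjusted p = 3.2e-06). Cell cycle genes rose in 15 of 49 cases and fell in 0, as also adjusted over the list alone (median 0.23, adjusted p = 0.000658), with Mcm2, a subunit of the replication helicase, at 0.77. The interferon response list went both ways, with 8 genes higher and 12 lower of 41 (9 and 14 adjusted over the list alone). Its median was 0.08 and its mean -0.12, and it did not pass the test (adjusted p = 0.607).

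Limma called 6901 probe sets here, 3761 higher and 3140 lower, and 13 of 22 lists. The groups lay in different wash runs, which cannot be told apart from the difference. The date as a block, which only sets 1 co-transfer array aside, gave 5719 calls. Both comparisons with mouse sites called 2368 probe sets higher and 2041 lower in common and 10 in opposite directions. Independent lists of these sizes would share 487 and 358. The fold changes correlated with r = 0.864 across probe sets, against 0.549 for simulated unchanged groups with the same mouse arrays, and their covariance was 0.2456 against 0.0214. With 1 mouse array for each comparison, r was 0.705, or 0.733 with the arrays exchanged. The covariance was then 0.2184 or 0.2239, so most of it did not rest on the noise of single mouse arrays. A deviation common to both mouse arrays, such as that of their Gapdh ratios, would still enter both comparisons.

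Rat sites with and without co-transferred mouse embryos were then compared on day 7. Interferon response genes were higher after co-transfer: 7 of 41 rose and 0 fell (15 and 0 adjusted over the list alone; median 0.25, camera adjusted p = 1.07e-11). Ifit3, an antiviral gene induced by interferon, was at 647 ± 85.4 (n = 3) against 234 ± 21.4 (n = 2), a log2 change of 1.27 (SE 0.11, adjusted p = 0.00121). Wfdc18, a small whey acidic protein family member, was lower at 440 ± 78.7 against 1874 ± 0.778 (log2 change -1.97, SE 0.16, adjusted p = 0.000806). Acod1, the enzyme that makes itaconate, was at 26.4 ± 3.70 against 117 ± 26.9 (log2 change -1.05). Tmem14c, a mitochondrial membrane protein gene, was at 1499 ± 59.4 against 130 ± 14.6 (log2 change 3.06, SE 0.13, adjusted p = 2e-05). It was low only in these rat sites, being at 664 to 1499 in the other 5 groups, and 3 of 8 probe sets of the MHC class I gene H2-D1 were high only there. The labels do not tell whether the recipients of these arrays differed, so no difference from them, Ifit3, Wfdc18 and the interferon list included, can be assigned to co-transfer alone.

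Smooth muscle genes were lower after co-transfer, with 2 of 28 called lower and 0 higher (11 and 0 adjusted over the list alone; median -0.26, adjusted p = 2.93e-09). Natural killer cell genes were lower, with 4 of 16 called lower and 0 higher (7 and 1 adjusted over the list alone; median -0.22, adjusted p = 0.000109). Among them, Gzmg changed by -0.71 (adjusted p = 0.00657) and Gzma by -0.68 (adjusted p = 0.00688). Without replicate 1 of the rat sites Gzmg had an adjusted p of 0.0526 and Gzma of 0.0665, and without replicate 2 of the rat sites 0.0676 and 0.0618. Endothelium and angiogenesis genes were lower in 2 and higher in 0 of 39 cases (9 and 1 adjusted over the list alone; median -0.16, adjusted p = 0.000253). The extracellular matrix list was lower in 3 and higher in 0 of 45 cases (8 and 2 adjusted over the list alone; median -0.12, adjusted p = 0.00079), a call lost with the estimated correlation (adjusted p = 0.139 with an estimated correlation). In the decidual stroma list 0 of 26 genes were called in either direction by limma, and 0 adjusted over the list alone (median 0.05, adjusted p = 0.37).

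Limma called 214 probe sets (127 higher, 87 lower), against 3174 at an unadjusted p under 0.05, and the groups lay in different wash runs. It was 34 and 35 without replicate 1 or 2 of the rat sites, 83, 140 and 96 without replicate 1, 2 or 3 of the co-transfer sites, 96 with the date as a block, 46 with the replicate number as a block, 76 with no filter, 122 without probe sets shared by transcripts, 333 with array weights and 25 with only these arrays. Of 26 named gene results, only those of Tmem14c, Ifit3, Wfdc18 and Acod1 kept their call with 1 array left out, the larger pseudocount, quantile normalization and the replicate block.

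On day 9 the comparison of rat with mouse sites showed low signals of decidual, trophoblast, yolk sac and embryonic blood genes in rat sites, together with high signals of epithelial and interferon response genes. Tdo2, the tryptophan-degrading dioxygenase of the decidua, was at 443 ± 71.6 (n = 2) against 10050 ± 37.6 (n = 2), a log2 change of -4.35 (SE 0.10, adjusted p = 4.75e-09), and Prl3c1 was at 49.1 ± 56.7 against 1634 ± 266. Prl4a1, a prolactin family gene of trophoblast, was at 286 ± 25.4 against 15910 ± 2564 (log2 change -5.53, SE 0.32, adjusted p = 1.04e-06). The collagenase Mmp13 was at 5837 ± 376 against 41.5 ± 4.60 (log2 change 5.90, SE 0.18, adjusted p = 2.29e-08). Muc1, a mucin of the luminal epithelium, was at 2518 ± 373 against 76.9 ± 16.5 (log2 change 4.26), and Krt20, an epithelial keratin, at 1260 ± 113 against 12.5 ± 2.69.

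Of 26 decidual stroma genes 17 fell and 7 rose, as also adjusted over the list alone (median -0.97, camera adjusted p = 2.65e-05). Of 28 trophoblast genes 20 fell and 5 rose (21 and 5 adjusted over the list alone; median -2.71, adjusted p = 2.09e-08). Genes of visceral endoderm and yolk sac fell in 19 and rose in 1 of 31 cases (20 and 4 adjusted over the list alone; median -0.84, adjusted p = 2.54e-07), with the fetal serum protein genes Afp (-5.03) and Ttr (-4.71). In the primitive erythroid list 8 of 17 fell and 1 rose (10 and 1 adjusted over the list alone; median -0.75, adjusted p = 0.00109), with the embryonic globin genes Hba-x (-5.50) and Hbb-bh1 (-5.03). The list of the embryo proper did not pass the test (1 rose and 4 fell of 14, median -0.07, adjusted p = 0.128). These 4 lists were chosen for embryonic genes, whose rat transcripts may bind mouse probes poorly. Part of the falls is built in, since genes high only on the mouse arrays of day 9 could pass the filter. The signals of these lists need not be embryonic in every case. Krt8, which also stands in the epithelium list, was at 13200 in rat sites. No value here tells rat from mouse transcripts. Natural killer cell genes, which are maternal, fell in 13 and rose in 0 of 16 cases, as also adjusted over the list alone (median -1.06, adjusted p = 1.62e-07), with the perforin gene Prf1 at -1.81. Angpt2, a vessel growth factor, was at 650 ± 0.424 in rat sites against 6655 ± 856 in mouse sites (log2 change -3.24, SE 0.14, adjusted p = 1.38e-07).

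Interferon response genes rose in 37 of 41 cases and fell in 0 (38 and 0 adjusted over the list alone; median 1.32, adjusted p = 4.33e-18). The GTPase gene Iigp1 was at 13960 ± 10.04 against 989 ± 226 (log2 change 3.76, SE 0.15, adjusted p = 1.02e-07). MHC class I presentation genes rose in 12 and fell in 0 of 17 cases (13 and 0 adjusted over the list alone; median 0.64, adjusted p = 7.94e-06), with the immunoproteasome genes Psmb8 (1.90) and Psmb9 (1.84). Epithelium and gland genes rose in 26 and fell in 3 of 33 cases, as also adjusted over the list alone (median 1.65, adjusted p = 9.34e-12). Smooth muscle genes rose in 20 and fell in 1 of 28 cases, as also adjusted over the list alone (median 0.66, adjusted p = 8.76e-07), with Oxtr, the oxytocin receptor, at 3.75 and the contractile protein gene Cnn1 at 1.30. Of 38 immediate early and heat shock genes 17 rose and 2 fell (21 and 2 adjusted over the list alone; median 0.33, adjusted p = 0.000249), with Hspa1a at 3.30. Neutrophil and acute inflammation genes rose in 11 and fell in 3 of 26 cases (12 and 4 adjusted over the list alone; median 0.69, adjusted p = 0.0125; adjusted p = 0.0821 with an estimated correlation), with the chemokine gene Cxcl2 at 3.32 and the decoy receptor gene Il1r2 at -3.95. Extracellular matrix genes rose in 21 and fell in 6 of 45 cases (24 and 7 adjusted over the list alone; median 0.33, adjusted p = 0.000141; adjusted p = 0.0656 with an estimated correlation), with Mmp10 (4.85), a stromelysin, and Tnc (3.72), the matrix protein tenascin C. The 18S rRNA middle signals of these rat sites, 6737.2 and 6209.4, stood apart from those of the other arrays.

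Adipocyte genes were high in the mouse sites of day 9. Adipoq, the fat cell hormone adiponectin, was at 1956 ± 125 there, against 113 ± 35.1 in rat sites and 30.5 ± 26.6 after co-transfer, and of 15 measured genes of the list 8 were lower and 2 higher in rat than in mouse sites (9 and 2 adjusted over the list alone; median -1.12, camera adjusted p = 0.00455). The call of this list was lost with the estimated correlation (adjusted p = 0.0526 with an estimated correlation). The share of fat in the samples was not measured, so the difference need not come from embryo species.

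Limma called 6982 probe sets between rat and mouse sites on day 9, 3788 higher and 3194 lower, of which 2219 changed at least 2-fold. The groups lay in different wash runs, which cannot be told apart from the difference, and only the arrays compared gave 4166 calls. The date as a block, which adjusts for no wash run here, gave 6916.

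Rat sites after co-transfer were next set against mouse sites on day 9: decidual genes were higher and embryonic genes lower. Prl3c1 was at 6322 ± 25.1 (n = 2) against 1634 ± 266 (n = 2), a log2 change of 1.92 (SE 0.29, adjusted p = 0.00335), and Wnt4, a signalling gene of decidualisation, was at 2363 ± 18.5 against 957 ± 36.4. Of 26 decidual stroma genes 7 rose and 0 fell (9 and 1 adjusted over the list alone; median 0.21, camera adjusted p = 0.00396). The embryonic globin gene Hbb-y was at 8.60 ± 1.13 against 23180 ± 1079 (log2 change -8.47, SE 0.15, adjusted p = 5.93e-10), and Prl4a1 at 34.2 ± 9.40 against 15910 ± 2564. The signals of both genes after co-transfer were below the pseudocount.

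Of 28 trophoblast genes 18 fell and 0 rose (19 and 0 adjusted over the list alone; median -1.93, adjusted p = 6.32e-29). Yolk sac and visceral endoderm genes fell in 19 and rose in 2 of 31 cases (20 and 2 adjusted over the list alone; median -1.08, adjusted p = 4.08e-18). Primitive erythroid genes fell in 7 and rose in 0 of 17 cases (10 and 0 adjusted over the list alone; median -0.77, adjusted p = 2.85e-10). Genes of the embryo proper fell in 4 and rose in 0 of 14 cases (9 and 0 adjusted over the list alone; median -0.70, adjusted p = 2.95e-05). The pluripotency and early embryo genes Lin28a (-3.44) and Sall4 (-2.83) led the last of these. The filter on dim probe sets let in genes high only on the mouse arrays of day 9, such as Lin28a and Sall4. Part of the fall of the embryonic lists is therefore built in, which the list p-values do not allow for. Adipocyte genes fell in 9 and rose in 0 of 15 cases (10 and 0 adjusted over the list alone; median -0.71, adjusted p = 4.45e-12). The mouse sites of day 9 had the Adipoq signal of 1956 ± 125.

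Among immune lists, natural killer cell genes fell in 5 and rose in 0 of 16 cases (8 and 0 adjusted over the list alone; median -0.40, adjusted p = 2.95e-05), with Gzma, granzyme A, at -0.93. Interferon response genes rose in 6 and fell in 0 of 41 cases (9 and 0 adjusted over the list alone; median 0.19, adjusted p = 0.000651), with Iigp1 at 1.06. Macrophage and dendritic cell genes fell in 7 and rose in 1 of 30 cases (7 and 2 adjusted over the list alone; median -0.21, adjusted p = 0.00208). H2-Eb1 of MHC class II, which presents antigen to T cells, went the other way at 1.71. Complement and coagulation genes fell in 7 and rose in 1 of 28 cases (12 and 1 adjusted over the list alone; median -0.36, adjusted p = 1.61e-05). Smooth muscle (2 rose and 1 fell of 28; adjusted p = 0.742) and hypoxia and glycolysis genes (3 rose and 3 fell of 37; adjusted p = 0.365) did not pass the test.

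Limma called 1708 probe sets, 873 higher and 835 lower, of which 305 fell and 140 rose at least 2-fold. With the date as a block, which adjusts for no wash run here, it called 1635. The number was 825 without replicate 2 of the mouse sites, 729 and 695 without replicate 1 or 2 of the co-transfer sites, 947 with no filter, 1037 without probe sets shared by transcripts and 375 with only these arrays, and the groups lay in different wash runs. On day 9 both groups of rat sites shared 337 probe sets called higher and 408 called lower than in mouse sites, against 149 and 120 for independent lists of these sizes, and 353 were called in opposite directions. Across probe sets, which are not independent replicates, the fold changes correlated with r = 0.346, against 0.501 in simulated unchanged groups that share the mouse arrays, and their covariance was 0.1171 against 0.0214. With 1 mouse array for each comparison, r was 0.191, or 0.264 with the arrays exchanged. The covariance was then 0.0746 or 0.0939, so part of it may come from the shared arrays. A deviation common to both mouse arrays would still enter both comparisons.

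The last comparison within a day asked what co-transferred mouse embryos changed at rat sites on day 9. Decidual genes were high and epithelial, inflammatory and interferon response genes low after co-transfer. Prl3c1 was at 6322 ± 25.1 (n = 2) against 49.1 ± 56.7 (n = 2), a log2 change of 6.02 (SE 0.29, adjusted p = 2.73e-07), and Tdo2 at 13550 ± 212 against 443 ± 71.6 (log2 change 4.77, SE 0.10, adjusted p = 5.36e-09). Cyp11a1, the enzyme that makes pregnenolone from cholesterol, was at 7052 ± 56 against 330 ± 14.2 (log2 change 4.20). Mmp13 was at 86.9 ± 5.66 against 5837 ± 376 (log2 change -5.35, SE 0.18, adjusted p = 4.14e-08), and the stromelysin gene Mmp3 changed by -4.15. Calb1, a calcium-binding protein of uterine epithelium, was at 117 ± 8.77 against 3096 ± 13.1 (log2 change -4.18, SE 0.10, adjusted p = 5.36e-09).

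**Figure D3:**
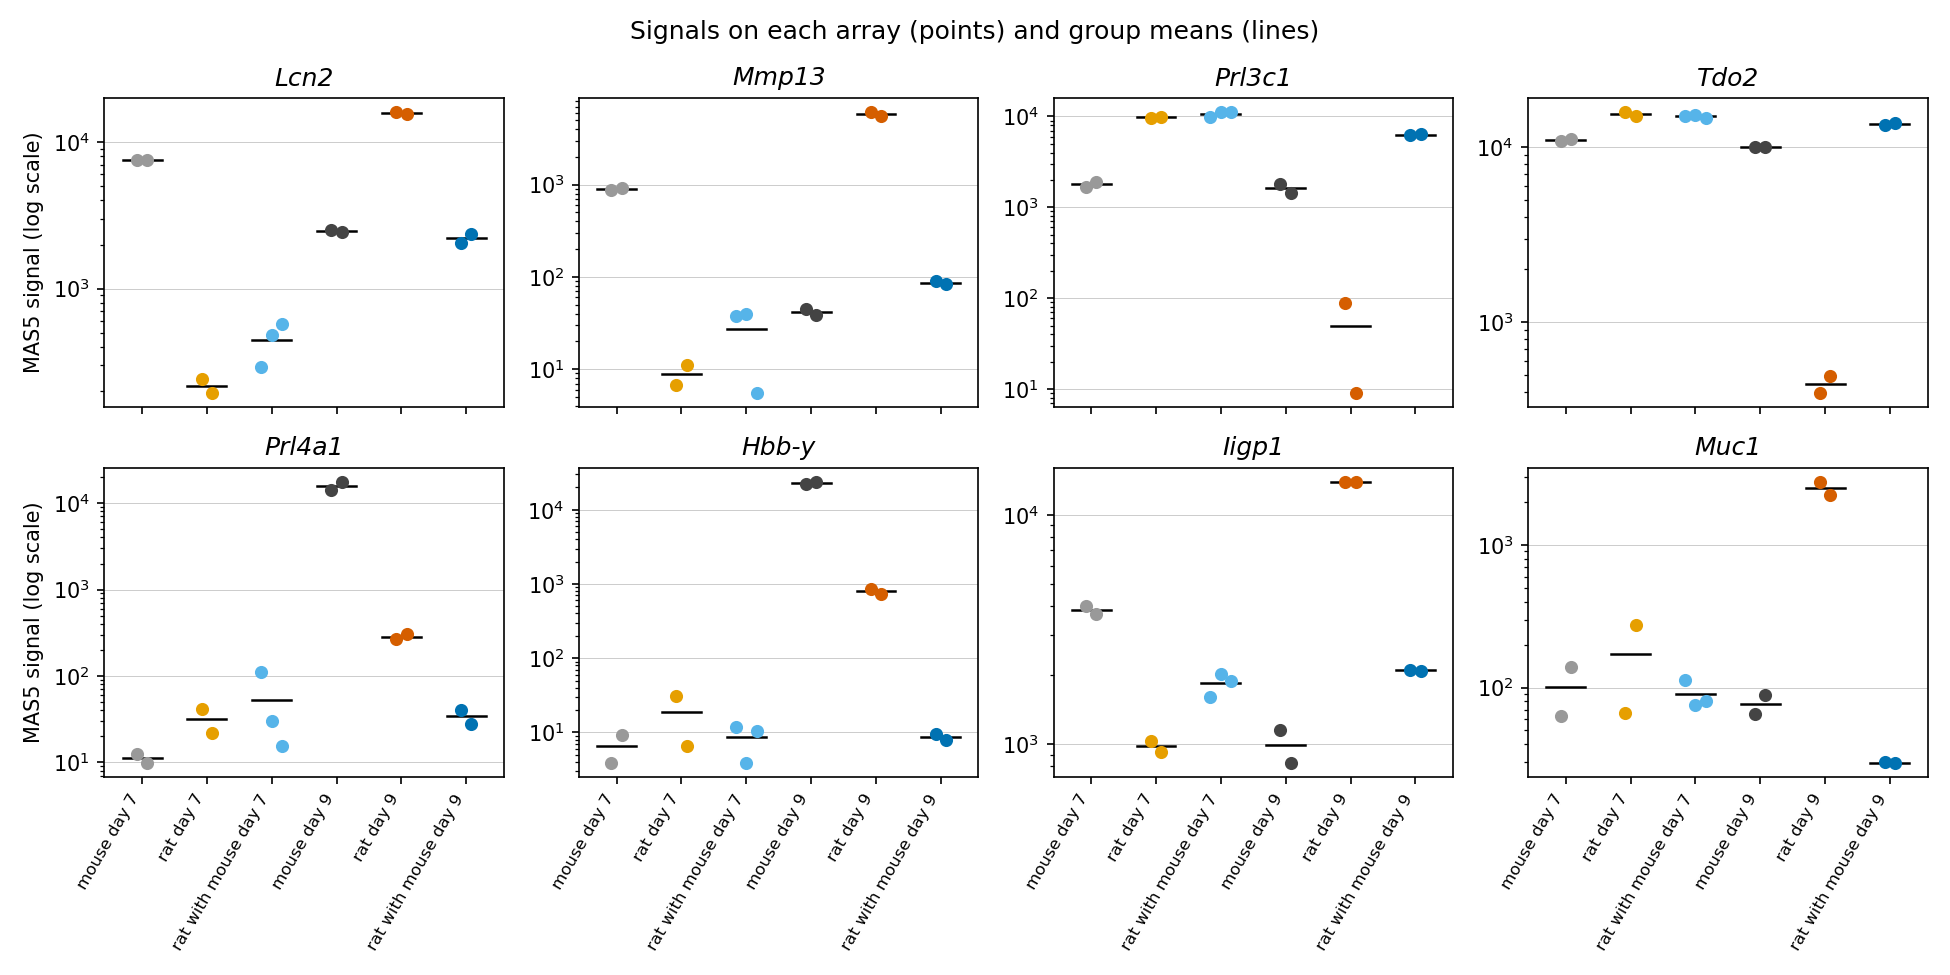
Points are MAS5 signals of single arrays on a log axis and lines the group means, for 8 named genes in the 6 groups. Prl3c1 and Tdo2 are low in the rat sites of day 9, at 49.1 and 443, while Lcn2, Mmp13, Iigp1 and Muc1 are highest there.

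Of 26 decidual stroma genes 18 rose and 6 fell (18 and 7 adjusted over the list alone; median 1.48, camera adjusted p = 4.01e-06). Natural killer cell genes rose in 12 and fell in 0 of 16 cases, as also adjusted over the list alone (median 0.66, adjusted p = 3.53e-05), with Prf1 at 1.14 and Gzmc at 1.00. Endothelium and angiogenesis genes rose in 19 and fell in 7 of 39 cases (20 and 7 adjusted over the list alone; median 0.27, adjusted p = 0.00437), with Angpt2 at 3.42 and the lymphatic vessel marker Lyve1 at 1.61. Epithelium and gland genes fell in 26 and rose in 2 of 33 cases (27 and 2 adjusted over the list alone; median -1.27, adjusted p = 1.56e-12). Interferon response genes fell in 35 and rose in 0 of 41 cases (37 and 0 adjusted over the list alone; median -1.25, adjusted p = 2.78e-15), with Igtp at -2.75. MHC class I presentation genes fell in 13 and rose in 1 of 17 cases, as also adjusted over the list alone (median -0.68, adjusted p = 2.33e-05). The rat sites that form the reference of these lists had 18S rRNA middle signals of 6737.2 and 6209.4, against 1338.7 and 1349.1 after co-transfer.

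Genes of neutrophils and acute inflammation fell in 13 and rose in 4 of 26 cases (15 and 4 adjusted over the list alone; median -0.86, adjusted p = 0.00162), with the calprotectin gene S100a9 at -3.38. Macrophage and dendritic cell genes fell in 15 and rose in 5 of 30 cases (16 and 5 adjusted over the list alone; median -0.67, adjusted p = 0.00437), with Cd74, the MHC class II invariant chain, at -1.88. Extracellular matrix genes fell in 24 and rose in 4 of 45 cases (27 and 4 adjusted over the list alone; median -0.52, adjusted p = 1.01e-05). Smooth muscle genes fell in 19 and rose in 2 of 28 cases, as also adjusted over the list alone (median -0.64, adjusted p = 2.33e-05), with Oxtr at -3.70. Cell cycle genes fell in 20 and rose in 3 of 49 cases (22 and 5 adjusted over the list alone; median -0.35, adjusted p = 0.00162), a call lost with the estimated correlation (adjusted p = 0.0584 with an estimated correlation); Rrm2, a subunit of ribonucleotide reductase, went the other way at 1.81. The trophoblast (7 rose and 11 fell of 28; adjusted p = 0.295) and yolk sac lists (3 rose and 9 fell of 31; adjusted p = 0.245) did not pass the test, while Hbb-y was at 8.60 ± 1.13 after co-transfer and 805 ± 90.4 in rat sites alone (log2 change -3.71).

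Limma called 7463 probe sets, 3472 higher and 3991 lower after co-transfer. All 4 arrays came from 1 wash run. Those arrays alone gave 6485 calls, and all 12 lists were called again in the same direction. The fold changes are the same in both fits, so this tries only another estimate of the spread. The date as a block, which only sets 1 co-transfer array of day 7 aside, gave 7397.

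**Figure D4:**
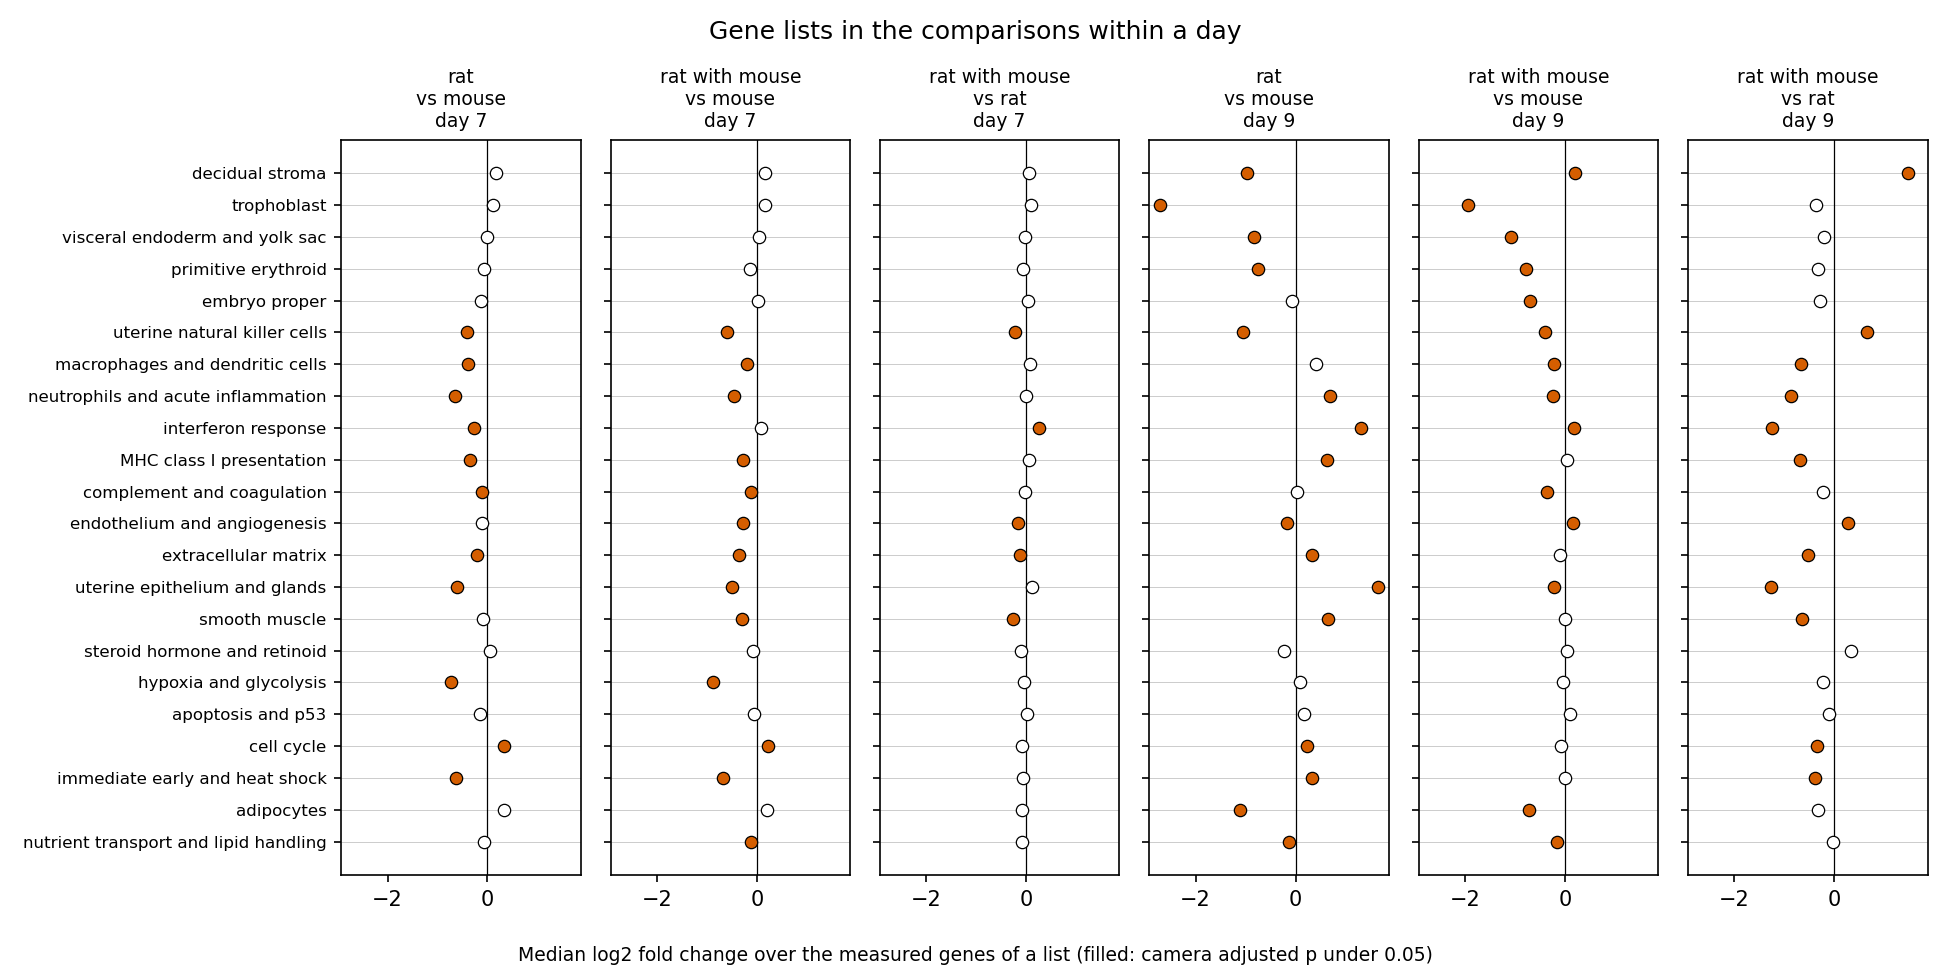
Each point is the median log2 fold change over the measured genes of a list in a comparison within a day, filled where camera's adjusted p was under 0.05. The interferon response list has medians of 1.32 in rat against mouse sites and -1.25 after co-transfer against rat sites on day 9.

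From day 7 to day 9, mouse sites gained transcripts of the growing embryo and placenta. Hbb-y changed by 8.51 on the log2 scale, to 23180 ± 1079 (n = 2). Prl7a1, a prolactin family gene of trophoblast giant cells, was at 11210 ± 195 on day 9 against 17.6 ± 10.6 on day 7 (n = 2; log2 change 7.24, SE 0.16, adjusted p = 2.49e-09). Trophoblast genes rose in 21 and fell in 2 of 28 cases, as also adjusted over the list alone (median 1.60, camera adjusted p = 1.87e-10). Part of this rise is built in, since genes high only on the mouse arrays of day 9 could pass the filter. Natural killer cell genes rose in 14 and fell in 0 of 16, as also adjusted over the list alone (median 1.26, adjusted p = 1.74e-08). Hypoxia and glycolysis genes fell in 28 and rose in 2 of 37 cases, as also adjusted over the list alone (median -0.66, adjusted p = 2.72e-08). Ptgs2 fell from 5252 ± 313 to 322 ± 105. Adipocyte genes rose as well, in 9 of 15 cases, and 1 fell, as also adjusted over the list alone (median 0.99, adjusted p = 0.000359), and Adipoq was at 44.2 ± 24.2 on day 7 and 1956 ± 125 on day 9. Adipoq was high in no other group. The share of fat in the samples was not measured, so the rise of adipocyte genes need not be a change with gestation. The mouse sites of day 7 with the low Gapdh ratios are the reference here.

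In rat sites over these days Prl3c1 fell from 9761 ± 143 to 49.1 ± 56.7 (log2 change -6.64, SE 0.29, adjusted p = 1.64e-07) and Tdo2 from 15500 ± 544 to 443 ± 71.6, while Mmp13 rose from 8.85 ± 3.04 to 5837 ± 376 and Lcn2 from 218 ± 33.2 to 15740 ± 339. All 41 interferon response genes rose, as also adjusted over the list alone (median 1.99, adjusted p = 1.33e-24). Of the decidual stroma list 16 of 26 genes fell and 7 rose (17 and 7 adjusted over the list alone; median -1.21, adjusted p = 0.000125). Macrophage and dendritic cell genes rose in 24 and fell in 0 of 30 cases, as also adjusted over the list alone (median 0.99, adjusted p = 1.03e-09). As in mouse sites, natural killer cell genes rose, in 12 of 16 cases, and 0 fell, as also adjusted over the list alone (median 0.55, adjusted p = 3.38e-05). Mouse and rat sites shared 1469 probe sets that rose and 1572 that fell between the days, against 974 and 948 for independent lists of these sizes, and 1717 went in opposite directions, with r = 0.135 across probe sets. The rat sites of day 7, whose recipients may differ from those of the other arrays, are the reference of the change in rat sites.

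Rat sites after co-transfer gained Akr1c18, the progesterone-degrading 20-alpha-hydroxysteroid dehydrogenase, at 4282 ± 15.5 on day 9 (n = 2) against 99.2 ± 57.4 on day 7 (n = 3), a log2 change of 4.86 (SE 0.27, adjusted p = 1.93e-06). Natural killer cell genes rose in 14 and fell in 0 of 16 cases (15 and 0 adjusted over the list alone; median 1.55, adjusted p = 2.19e-14). Interferon response genes rose in 20 and fell in 0 of 41 (22 and 1 adjusted over the list alone; median 0.62, adjusted p = 1.55e-08). Cell cycle genes fell in 37 and rose in 0 of 49 (40 and 0 adjusted over the list alone; median -0.78, adjusted p = 5.01e-15). The trophoblast list had a median of -0.04 (7 rose and 5 fell of 28; adjusted p = 0.694).

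Between the days limma called 9789 probe sets in mouse sites, 8704 in rat sites and 5576 in rat sites after co-transfer, and 9776, 8684 and 4836 with the date as a block. The last number was 3295 and 3351 without replicate 1 or 2 of the day 9 sites and 3622 without probe sets shared by transcripts, and day and wash run cannot be told apart in any of the 3 groups.

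The interaction with day was called in 7206 of 22155 probe sets for rat against mouse sites. Rat and mouse sites differed on both days in 2651 probe sets, of which 1840 went in opposite directions on day 7 and day 9. Independent lists of these sizes would give 413 and 431 calls in the opposite directions, and simulated unchanged groups gave a correlation of -0.002 between the fold changes of the days, where the observed r across probe sets was -0.252. Rat sites after co-transfer differed from mouse sites on both days in 601 probe sets in the same direction (343 higher and 258 lower, against 148 and 118 for independent lists) and in 274 in opposite directions, with r = 0.085. Lcn2 was at 7520 ± 15.5 in mouse and 218 ± 33.2 in rat sites on day 7, and at 2474 ± 68.9 and 15740 ± 339 on day 9. The difference of its log2 changes between the days was 7.43 (SE 0.32, adjusted p = 1.67e-07).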

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

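The tests of probe binding, carried RNA, 3' bias, wash run and share of epithelium were chosen only after the result was seen, while the interaction tests and those of an earlier stage and of exchanged labels were planned. A test of the interaction with day brought out the counts and the gene values of the first paragraphs, and the 3 patterns after them were picked from the comparisons after their values were seen. The difference between rat and mouse sites changed between day 7 and day 9 in 7206 probe sets, that between rat sites after co-transfer and mouse sites in 4163, and that between rat sites with and without co-transfer in 5778. The number for rat sites after co-transfer against mouse sites was 2490 without replicate 2 of the mouse sites of day 7, 2675 without replicate 2 of the mouse sites of day 9, and 2563 and 2433 without replicate 1 or 2 of the co-transfer sites of day 9. Of 271 gene results named within a day, 233 were called by this test, but they had been chosen for large differences on 1 day, which favours such a call.

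As differences of log2 fold changes (day 9 minus day 7), rat against mouse sites gave Mmp13 9.75, Mmp10 8.38, Lcn2 7.43, Mt4 -6.60, Prl3c1 -6.50 and Psca -6.00. Rat sites after co-transfer against mouse sites gave Sprr2f 4.69, Mmp10 4.25, Mmp13 4.06, Hbb-y -8.51, Prl4a1 -8.03 and Hbb-bh1 -7.67. Rat sites after co-transfer against rat sites gave Prl3c1 5.89, Angpt4 5.40, Psca 5.37, Mmp13 -5.69, Muc1 -4.41 and Calb1 -4.38.

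Lists of trophoblast, yolk sac and primitive erythroid genes were low in both groups of rat sites on day 9. Poor binding of rat transcripts to mouse probes may account for part of this and stays open: its test, the ratio of the highest to the lowest share of the mouse signal kept after co-transfer by probe sets of 1 gene (median 3.27), is void, since signals such as 8.60 for Hbb-y lie below the pseudocount. RNA of mouse sites carried into the rat samples of day 9 could account for part of the signals that remain: the lowest share of the mouse signal with no background subtracted, an upper limit for a carried share, was 1.39% in 1 probe set of Hbb-y, while another of Hbb-y kept 3.47%. With the co-transfer arrays as background the shares of 12 probe sets ran from -0.197% ± 0.31 (Ttr) to 3.44% ± 0.39 (Hbb-y), with a median of 1.9, and this too is open, since that background is an assumption. The amount and the species of embryo tissue were not tested apart. Part of the low list signals is also built in by the filter, which let in genes high only in mouse sites of day 9.

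Mouse sites of day 7 stood apart from both groups of rat sites of that day. A general 3' bias of their RNA is unlikely to account for it, since the ratios of 2 control genes moved opposite ways. Their Actb ratio was higher (3.59 ± 0.17, n = 2, against 2.62 ± 0.21, n = 5) and their Gapdh ratio lower (1.49 ± 0.071 against 3.01 ± 0.45). RNA quality was not tested otherwise and stays open. The 18S rRNA 3' signals of these mouse sites were low, at 2461.6 and 1072.8 against 3684.4 to 5756.1 on the other arrays of both days. An earlier stage of the mouse sites would give a positive correlation between the rat minus mouse change and the change with day in the co-transfer group, and r was -0.11. A later stage of the mouse sites would give a negative r and was not tested, so a difference in stage stays open. Day and wash run cannot be told apart in that change with day. Wash run cannot account for the difference from rat sites alone, as 4069 probe sets were called with the 4 arrays of 1 run, but for the co-transfer sites it remains possible. Embryo species is a biological difference the design gives, together with embryo age (flushed on day 4 or day 5), and the time from dissection to freezing is not given in the sources used here. The recipients of the rat sites of day 7 may differ as well, since several H2-D1 probe sets were high and Tmem14c was low only there. This limit also holds for the change with day in rat sites and for the interactions that include it.

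Epithelial genes were high both in the mouse sites of day 7 and in the rat sites of day 9. Of 26 that were higher in rat sites than after co-transfer on day 9, 22 (84.6%) were higher in mouse than in rat sites on day 7, 18 of them called, and 1, Cldn3, was called the other way (-0.39, adjusted p = 0.0259). A larger share of otherwise unchanged epithelium would move them alike only if their signals came from epithelium alone. Their log2 differences on day 7 had an SD of 1.19 against a median SE of 0.13 and ran from -0.51 to 4.79. In whole sites this spread cannot decide, since other cells may add to the signal of each gene to an unequal extent. Muc1 was at 101 in mouse sites of day 7 and 2518 in rat sites of day 9. Krt7 was at 2603 in mouse and 938 in rat sites on day 7 and Pigr at 2046 and 1823, and 5 of the 26 genes stand in another list too. A larger share of epithelium and changes within it cannot be told apart here. Exchanged labels of these groups would make rising genes higher in the arrays labelled mouse day 7, but 93 of 130 probe sets (71.5%) were higher in the rat sites of day 9.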

How the results depend on the processing

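The fit without both arrays of the mouse sites of day 7 and the overlaps with 1 mouse array for each comparison were chosen only after the results were seen, and the other alternatives were planned. No call of a named gene or list turned in direction. Named genes were run with 1 array left out, the larger pseudocount, quantile normalization and the replicate block only: of 313 results 267 kept their call in all of these, and the 46 others lost it when 1 array was left out. Leaving 1 array out gave 3066 to 3772 calls for rat against mouse sites on day 7, 3867 to 6404 for rat sites after co-transfer against mouse sites, and 34 to 140 for rat sites after co-transfer against rat sites. On day 9 the co-transfer sites against mouse sites gave 695 to 1785, the change with day after co-transfer 3295 to 4862, and its interaction with mouse sites 2433 to 4173. A lone array left in a group is assumed to vary like the other groups. For co-transfer against rat sites on day 7 the count was 76 with no filter, 122 without probe sets shared by transcripts, 46 with the replicate number and 96 with the date as a block, 333 with array weights and 25 with only the arrays compared, against 214. For co-transfer against mouse sites on day 9 it was 947 with no filter, 1037 without shared probe sets and 375 with only the arrays compared, against 1708. Rat against mouse sites on day 9 gave 4166 with only the arrays compared, the change with day after co-transfer 3622 without shared probe sets, and the interaction of co-transfer against mouse sites 2446 with no filter. The cause was not tested. Probe sets shared in the same direction by both comparisons with mouse sites fell from 4409 on day 7 to 2286 and 2412, and from 745 on day 9 to 559 and 370, with 1 mouse array for each comparison. All other counts stayed within 1.5 times. With quantile normalization 51.1% of the calls between rat sites after co-transfer and rat sites on day 9 were higher, against 46.5%, and 45.3% against 51% for the change with day in rat sites, so which direction prevails there depends on the scaling, as in the 3 interactions. With no filter 44.7% of the calls between co-transfer and rat sites on day 7 were higher, against 59.3%. For co-transfer against mouse sites on day 9 it was 41.1% with no filter and 47.4% with the replicate block, against 51.1%. Replicate numbers did not pair across groups: over 15 pairs of groups r between arrays of the same number ran from -0.206 to 0.091. Signals near the pseudocount of 57.1 limit what dim genes can show.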

Other observations

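No test in this part was chosen after its result was seen, and the genes were picked for their profiles over the 6 groups after their values were seen. The planned list of steroid hormone and retinoid genes did not pass the test between rat and mouse sites (adjusted p = 0.829 on day 7 and 0.0744 on day 9). Cyp11a1, which starts steroid synthesis, was at 4757, 4203 and 3847 in mouse sites, rat sites and rat sites after co-transfer on day 7, and at 5730, 330 and 7052 on day 9. Cyp17a1, which makes androgens, was at 1986 ± 119 in mouse sites of day 9 (n = 2) and at 37.6 or less in every other group. Whether embryo or mother made this transcript was not tested. Poor binding of rat transcripts therefore stays open for its low signals in rat sites. Akr1c18, which degrades progesterone, was at 4164 in mouse sites, 643 in rat sites and 4282 after co-transfer on day 9.

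Fkbp5, a chaperone of steroid receptors, was at 693, 3176 and 2563 on day 7 and at 2297, 842 and 3470 on day 9 in the same order. Zbtb16, a transcription factor induced by progesterone, was at 430, 2347 and 2517 on day 7 and at 2016, 394 and 2218 on day 9. Lipg, an endothelial lipase, was at 20130 in mouse sites, 920 in rat sites and 13620 after co-transfer on day 9, and between 946 and 1383 on day 7. The gland protease gene Prss28 was at 21450, 18920 and 18190 on day 7 and at 1064, 8982 and 7136 on day 9.

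For H2-D1, 3 of its 8 probe sets were high in rat sites of day 7 (1549 ± 5.59, 1714 ± 15.4 and 1960 ± 35.9, n = 2) and at most 81.5, 317 and 55.9 in other groups, while the 5 others were lower in rat than in mouse sites of day 7, such as 5122 ± 125 against 10210 ± 175. Tmem14c was at 130 ± 14.6 there against 664 to 1499 elsewhere.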
